A study of Mus musculus with 8 samples.

How the data were processed

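Peripheral retina was dissected from mouse embryos at embryonic day 16.5, and 4 libraries labelled as conditional knockout and 4 labelled as control were sequenced. Per the labels' protocols, RNA was purified with a column kit and 1 μg of total RNA went into a standard Illumina library; whether the library marks strand is not given in the sources used here. Replicates are separate samples in the labels. Nothing in the labels says which embryo or litter each came from, so p-values measure the spread between these samples.

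The authors deposited a single table of 16096 genes. Reads were aligned with Novoalign 2.08.01 to mm10 and tested with DESeq2, per the submitters' processing notes; the counter, annotation release and filter are not given in the sources used here. The deposited counts are whole numbers per gene and library, not normalized, with 13994825 to 18391647 per library and a lowest row sum of 18, so genes with few reads were left out of the table. The authors' FPKM columns are scaled by gene model length and by counted reads; the gene length they imply is 1.00 times the exon union of GENCODE release M21 (median). The authors' log2 ratio column compares the groups. The authors' adjusted p column is a score on an unnamed scale; its slope on the -log10 adjusted p of a DESeq2 fit made here was 11.2 (r = 0.961 across genes, which are not independent replicates). Read as 10 times the negative log10, the authors' deposited table calls 1182 genes higher and 560 lower, and 1552 of the 1773 calls made here were called the same way there. No column was left without a sample. The FPKM, ratio and score columns were used only for these checks.

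Coordinates, strand and overlaps came from GENCODE M21 on the mm10 assembly, matched by Ensembl identifier; 15833 identifiers matched and 263 did not. Where 1 of the 66 repeated symbols was looked up, the row with the most counts was used.

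The test of each gene was edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr with its minimum count of 10, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. It used 4 against 4 libraries and no covariate. The filter left 15014 genes, with 99.9% of the counts, and left out 1082. Normalization factors ran from 0.955 to 1.04. Standard errors are those implied by the quasi-likelihood F statistic, and 95% limits use the residual degrees of freedom. Levels are CPM on normalized library sizes, except that levels summed over a list divide by total counts. A fold against a control group at 0 was computed against a floor of 3 counts over the group; for 1 to 3 control counts the ratio has an exact 95% binomial interval. Such floors and intervals cover counting error only. A count of 3 in a library is 0.163 to 0.214 CPM.

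Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists cover PRC2 and PRC1 components, cyclin-dependent kinase inhibitors, cell cycle, progenitors, late progenitor factors, Müller glia, ganglion, horizontal, amacrine, cone, rod and bipolar cells, ciliary margin, dorsoventral patterning, Hox genes, regulators of other lineages, germline, p53 targets, Wnt, and, for other cell types and quality, pigment epithelium, lens, erythroid, endothelial, mesenchyme, microglia, immediate early, mitochondrial and sex-linked genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry. Of the 17 lists called, 9 held with an estimated correlation and 15 with fry. Fry asks whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. The named genes were Ezh2; the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM and no overlap between groups; up to 4 members of each list with the smallest p; and the 5 called genes with the smallest p in each direction. The rule gave 130 genes; after their values were seen, genes named only through the 6 lists without a called member were described by list, and certain genes are not reported here, which left 106.

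Embryo sex was read from Xist and 4 Y-linked genes. The 8 libraries were compared pair by pair within each group with a chi-square test. They differed by 4.90 to 25.2 per degree of freedom, so no library was taken for a repeat of another. Control replicates 1 and 3 (4.90) and 2 and 4 (9.66) were more alike than the other control pairs (18.5 to 25.2). Mitochondrial rRNA made up 13.7% and 13.5% of the counts in control replicates 1 and 3, and 8.72% and 8.19% in 2 and 4. The labels give no batch, and the cause of this division was not tested. The Ezh2 test was repeated as an exact permutation test of log2 CPM.

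The procedure was tested on simulated counts with 200 changed genes among 15014, drawn from the means, sizes and dispersions of these libraries. It called 30% of the genes changed 1.25-fold, 72% at 1.5-fold and 100% at 2-fold and at 4-fold, in the right direction. Of 163 calls, 12 (7.36%) were unchanged genes. With no gene changed it called 3 genes and 1 list. The simulated genes were drawn independently of each other, so the simulation does not cover lists whose genes are correlated.

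Alternatives were 3 normalizations, DESeq2 1.42.0, limma-voom, filters on low counts, thresholds, a replicate block, a surrogate variable (sva 3.50.0), each library left out, and, added after the data were seen, the male libraries alone, sex as a covariate, omission of the 2 libraries with lens crystallin counts, omission of genes on X and Y, and the share of mitochondrial rRNA as a covariate. Figures were drawn with matplotlib 3.10.9.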

Results

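RNA was sequenced from the peripheral retina of C57BL/6 mouse embryos at embryonic day 16.5. The Pax6alpha-Cre driver, active in the peripheral retina, was combined with an Ezh2 allele flanked by loxP sites and either a null allele (4 conditional knockout libraries, labelled cKO) or a wild-type allele (4 control libraries). Ezh2 encodes the histone H3 lysine methyltransferase of Polycomb repressive complex 2 (PRC2). By the labels both groups carry Cre. Where Cre acts, the comparison is thus meant to set loss of both Ezh2 alleles against loss of the floxed allele alone. Cells without active Cre carry a null allele in the cKO libraries only. The comparison addresses which transcripts in the developing retina differ between these genotypes. Total counts per library ran from 13994825 in control replicate 1 to 18391647 in cKO replicate 1. The mitochondrial 16S rRNA mt-Rnr2 was the most counted gene in each library, with 7.56% to 13.2% of the counts.

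The whole-gene count of Ezh2 itself was not lower in the labelled-cKO libraries. Ezh2 (ENSMUSG00000029687, mm10 chromosome 6, 47530139 to 47595341, minus strand) stood at 276, 251, 255 and 220 CPM (counts scaled by the normalized library size) in cKO replicates 1 to 4 and at 235, 230, 197 and 207 CPM in control replicates 1 to 4. The group means were 251 ± 23.1 and 217 ± 18.1 CPM (SD, n = 4 each). The log2 fold change was 0.21 (SE 0.07, 95% limits 0.04 to 0.38; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0701), and the exact two-sided permutation test over 70 assignments gave p = 0.0857, where the smallest possible p is 0.0286. The authors' deposited table lists a log2 ratio of 0.20 for Ezh2, and its score, read as 10 times the negative log10, gives an adjusted p of 0.0429 (DESeq2). The counts sum reads over the whole gene, and the deleted part is not given in the sources used here, so they do not check a deletion of single exons. Every direction below is therefore that of the libraries labelled cKO against the libraries labelled control. Of the 11 PRC2 components tested, 1 was higher, 1 was lower and 9 were not called (2 and 1 adjusted over the list alone). The higher member was Phf19, at log2 0.64. The lower was Aebp2, at log2 -0.24, a call lost in 13 of 22 alternatives, among them male libraries alone at -0.14. The list median was -0.02 and its mean 0.05, and camera, which compared the list with all other genes, gave an adjusted p of 0.854 in the lower direction, whereas fry gave the higher direction with an adjusted p of 0.891.

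**Figure D1:**
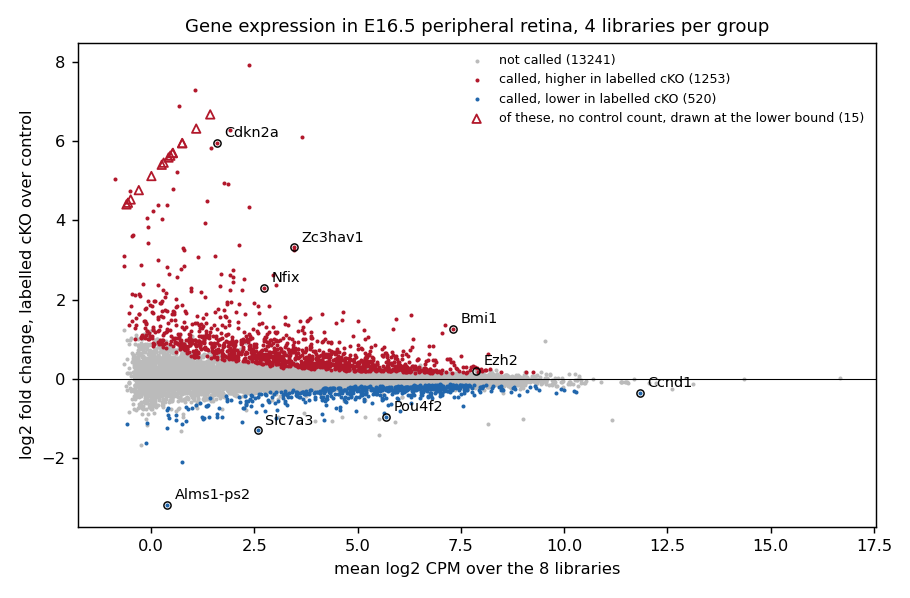
Each point is a gene, with the mean log2 CPM over the 8 libraries on the x axis and the log2 fold change of labelled-cKO over control libraries on the y axis. Red marks the 1253 genes called higher and blue the 520 called lower; the 15 genes without a control count are triangles at their lower bound, and fitted values of other genes with very few control counts are imprecise.

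Far more genes rose than fell in the labelled-cKO libraries, and the increases were larger. Among 15014 genes tested, 1253 were higher and 520 lower at an adjusted p under 0.05 (edgeR), so that 70.7% of the 1773 calls were higher. With counts scaled by library size alone the share was 82.5%. The median log2 fold change was 0.59 among the higher calls and -0.29 among the lower calls. A change of at least 2-fold was seen for 294 of the higher and 13 of the lower calls. Of the 1253 higher calls, 185 had a mean control level under 1 CPM, and 15 had no control count at all, all of them Hox genes. Of the 520 lower calls, 13 had a mean labelled-cKO level under 1 CPM. The first principal component, with 41.6% of the variance over 6397 genes, separated the groups. Among the 5 higher calls with the smallest p were Bmi1, Zc3hav1, Sall1 and Gm10567. The zinc finger antiviral protein gene Zc3hav1 reached 19.7 ± 2.42 CPM against 1.97 ± 0.367 (SD, n = 4), and Sall1, a zinc finger developmental regulator, rose by log2 2.62 (SE 0.11). Gm10567 was at 7.64 ± 0.647 against 0.729 ± 0.0995 CPM.

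Xist and the Y-linked genes showed that the embryo sexes were not balanced. Xist counts were 1874 and 1714 in cKO replicates 2 and 3, and at most 4 in each of the other 6 libraries. The 4 Y-linked genes summed to 202 to 236 CPM in those 6 libraries and to 0.745 and 0.800 CPM in cKO replicates 2 and 3. All 4 controls and cKO replicates 1 and 4 were thus male. With the 6 male libraries alone, 800 genes were higher and 255 lower, and 978 of the 1773 calls remained, with no call changing direction. The count of lower genes was 329 without control replicate 3 and 323 without cKO replicate 2 and control replicate 1, the 2 libraries with lens crystallin counts.

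Hox genes, which pattern the body axis, were counted in each labelled-cKO library and were nearly absent from the controls. All 18 Hox genes tested were called higher (18 adjusted over the list alone), and 15 of them had no count in any control. The list held 39 Hox genes, of which 16 were absent from the deposited genes and 5 were not tested. A gene without control counts passes the filter only through its labelled-cKO counts. The share of 18 in 18 and the list test below were therefore in part fixed by the filter. The summed level of the 23 Hox genes in the table was 53.1 ± 9.02 CPM in the labelled-cKO libraries and 0.137 ± 0.125 CPM in the controls (SD, n = 4). Against a floor of 3 counts over the control group, Hoxb7 was at least 102-fold higher, Hoxb8 at least 79.4-fold, Hoxc4 at least 61.7-fold, Hoxb3 at least 61.4-fold, Hoxb5 at least 52.0-fold, Hoxb6 at least 51.6-fold, Hoxa7 at least 49.4-fold and Hoxb4 at least 47.9-fold. Hoxb9 had 246 counts against 1, a ratio of 232 with an exact 95% counting interval of 41.3 to 9216. Hoxb2 was at 7.08 ± 1.98 against 0.0912 ± 0.111 CPM. The list median of the log2 fold change was 5.66 with the members at 0 placed at their bound. Camera gave an adjusted p of 1.75e-96 with the preset correlation and 0.00505 with an estimated correlation.

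The Hox counts came from the clusters on chromosomes 6, 11 and 15. The Hoxb genes on chromosome 11 summed to 2055 counts in the labelled-cKO libraries and 6 in the controls, the Hoxc genes on chromosome 15 to 675 and 1, and the Hoxa genes on chromosome 6 to 641 and 1. The measured Hoxb genes lie between 96194316 and 96354012 (mm10), all on the plus strand. The antisense transcript Hoxb3os (96343072 to 96354691, minus strand) had 632 counts against 2 and overlaps Hoxb2 and Hoxb3. Whether counting used strand is not given in the sources used here, so the counts of these 3 genes may include shared reads.

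**Figure D2:**
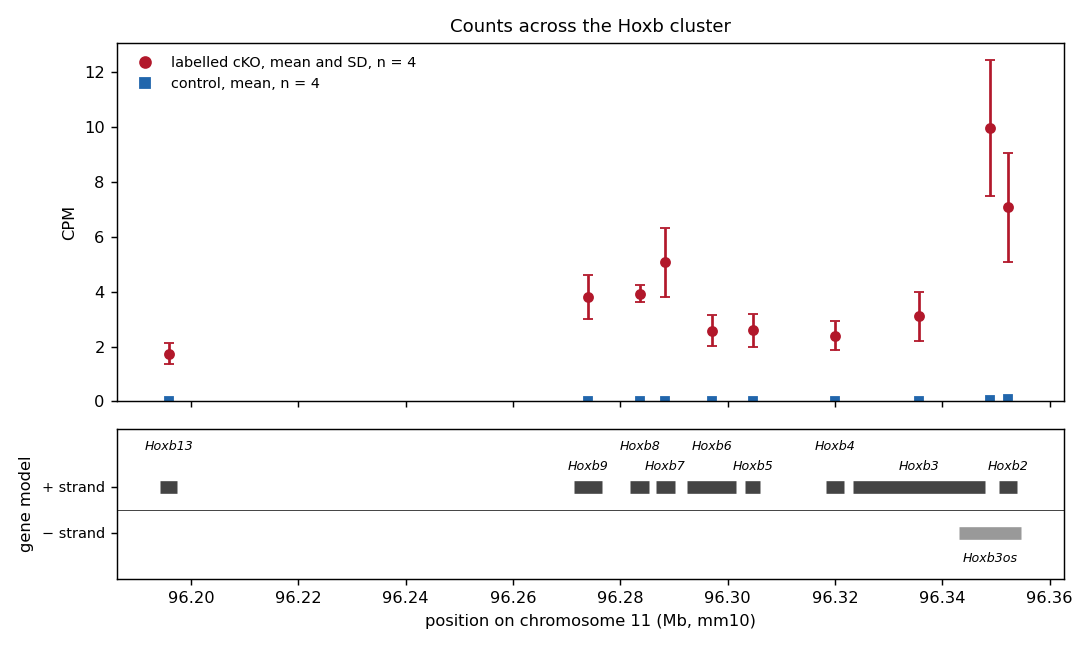
The upper panel gives the CPM (y axis) of each gene of the Hoxb cluster, as mean and SD of the 4 labelled-cKO libraries and the mean of the 4 controls, at the middle of its gene model; the x axis is the position on chromosome 11 in Mb. The labelled-cKO means run from 1.74 CPM for Hoxb13 to 9.96 CPM for the antisense Hoxb3os, and no control mean exceeds 0.0912 CPM; the lower panel gives the gene models by strand.

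Most transcription factors of other lineages that were tested rose in the same libraries. The list held 69 regulators, of which 43 were absent from the deposited genes and 7 were not tested. Regulators with very few control counts pass the filter through their labelled-cKO counts, so the share called was in part fixed by the filter. Of the 19 tested members of the list of developmental regulators of other lineages, 13 were higher, 1 was lower and 5 were not called (13 and 2 adjusted over the list alone), with a median log2 fold change of 1.92 (camera adjusted p = 2.73e-30; 0.000648 with an estimated correlation). Pax8, a thyroid and kidney regulator, rose by log2 4.79 from 0.0816 CPM, the stomach regulator Barx1 by 4.38 from 0.0993 CPM, and the limb mesenchyme gene Prrx1 by 1.93 from 1.40 CPM. Of the 9 mesenchyme and fibroblast genes tested, 3 were higher and 6 not called (3 adjusted over the list alone; median 0.66; camera adjusted p = 0.000279; adjusted p = 0.101 with an estimated correlation). The higher members were the transcription factors Twist1 (log2 3.83) and Foxc1 (2.63) and the growth factor receptor Pdgfra (1.01). Postn, a matrix protein gene, was at log2 0.66 (edgeR adjusted p = 0.323) and passed without cKO replicate 1 (edgeR adjusted p = 0.0206, in a range of 0.0206 to 0.826 over 22 alternatives). The list median was 0.997 without cKO replicate 1, 0.44 without cKO replicate 4 and 0.30 with the male libraries alone.

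Most cyclin-dependent kinase inhibitor genes rose. Of 7 cyclin-dependent kinase inhibitors, 5 were higher, 1 lower and 1 not called (5 and 1 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 1.19e-10; 0.00514 with an estimated correlation). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which encodes p16 and p19 proteins, rose from 0.0864 ± 0.0715 to 5.59 ± 0.895 CPM (log2 5.95, SE 0.33, edgeR adjusted p = 2.77e-08). Its neighbour Cdkn2b rose by log2 2.39, Cdkn1a by 1.21 and Cdkn1c by 0.50. The lower member was Cdkn1b, at log2 -0.21, named here after its values were seen, a call lost in 8 of 22 alternatives. Of 12 tested p53 targets and apoptosis genes, 9 were higher, 1 was lower and 2 were not called (9 and 1 adjusted over the list alone; median 0.49; camera adjusted p = 4.12e-16; 0.00505 with an estimated correlation). The death receptor gene Eda2r rose by log2 3.26, Phlda3, an inhibitor of Akt, by 1.63, and cyclin G1 (Ccng1) by 0.83. Cdkn1a belongs to both lists.

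Some genes of retinal progenitors fell by small amounts. Of 18 progenitor genes, 0 were higher, 7 were lower and 11 were not called (0 and 11 adjusted over the list alone), with a median log2 fold change of -0.17 (camera adjusted p = 1.31e-06; 0.0324 with an estimated correlation). Nr2e1, a nuclear receptor gene of progenitors, was at 42.4 ± 3.95 against 56.3 ± 2.30 CPM (log2 -0.41), and Id1 at log2 -0.41. Neurog2 was at log2 -0.29, a call that ended with sex as a covariate at log2 -0.25. Of 28 cell cycle and DNA replication genes, 1 was higher, 7 were lower and 20 were not called (1 and 7 adjusted over the list alone; median -0.10; camera adjusted p = 0.000556; adjusted p = 0.328 with an estimated correlation). Cyclin D1 (Ccnd1) fell from 4102 ± 131 to 3217 ± 183 CPM, a log2 change of -0.35 (edgeR adjusted p = 0.00189), and the licensing factor gene Cdt1 was at -0.30.

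Several factors of late progenitors and of glia rose. Of 9 late progenitor and gliogenic factors, 5 were higher, 2 lower and 2 not called (5 and 2 adjusted over the list alone; median 0.50; camera adjusted p = 2.00e-07; 0.0180 with an estimated correlation). Nfix rose from 2.15 ± 0.420 to 10.7 ± 1.30 CPM (log2 2.29), Hey2 rose by log2 1.19, Nfib by 0.81 and Hey1 by 0.50, whereas Sox9 and Id2 were at -0.38 and -0.33, members named here after their values were seen. Of 14 Müller glia genes, 6 were higher, 1 lower and 7 not called (8 and 2 adjusted over the list alone; median 0.19; camera adjusted p = 0.000667; adjusted p = 0.0903 with an estimated correlation). The higher members included the thyroid hormone binding protein gene Crym (117 ± 18.6 against 38.4 ± 1.96 CPM, log2 1.61), the water channel gene Aqp4 (1.54) and Clu (0.68).

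Some ciliary margin genes and most Wnt pathway genes tested rose. Of 12 ciliary margin genes, 6 were higher, 0 lower and 6 not called (7 and 0 adjusted over the list alone; median 0.59; camera adjusted p = 2.18e-09; 0.0109 with an estimated correlation). Cyclin D2 (Ccnd2) rose from 11.8 ± 2.11 CPM by log2 1.69 (SE 0.13), Mecom rose by log2 1.56, Wfdc1 by 0.82 and the transcription factor Zic1 by 0.82. Of 11 Wnt pathway genes, 7 were higher, 0 lower and 4 not called (8 and 1 adjusted over the list alone; median 0.49; camera adjusted p = 1.85e-05; 0.0155 with an estimated correlation). Notum, a secreted Wnt inhibitor, rose by log2 1.21, the ligand gene Wnt5a by 0.98, the transcription factor Lef1 by 0.71 and the inhibitor Sfrp1 by 0.33. Of 13 dorsal and ventral patterning genes, 3 were higher, 1 lower and 9 not called (6 and 2 adjusted over the list alone), with a median of -0.01, a mean of 0.15 and a camera adjusted p of 0.697 in the higher direction. The ventral gene Aldh1a3 was at log2 -0.46, the ventral gene Vax1 at 0.64 and the dorsal gene Tbx5 at 0.50, so ventral genes moved in both directions. The call of Vax1 ended with the male libraries alone, at log2 0.66.

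**Figure D3:**
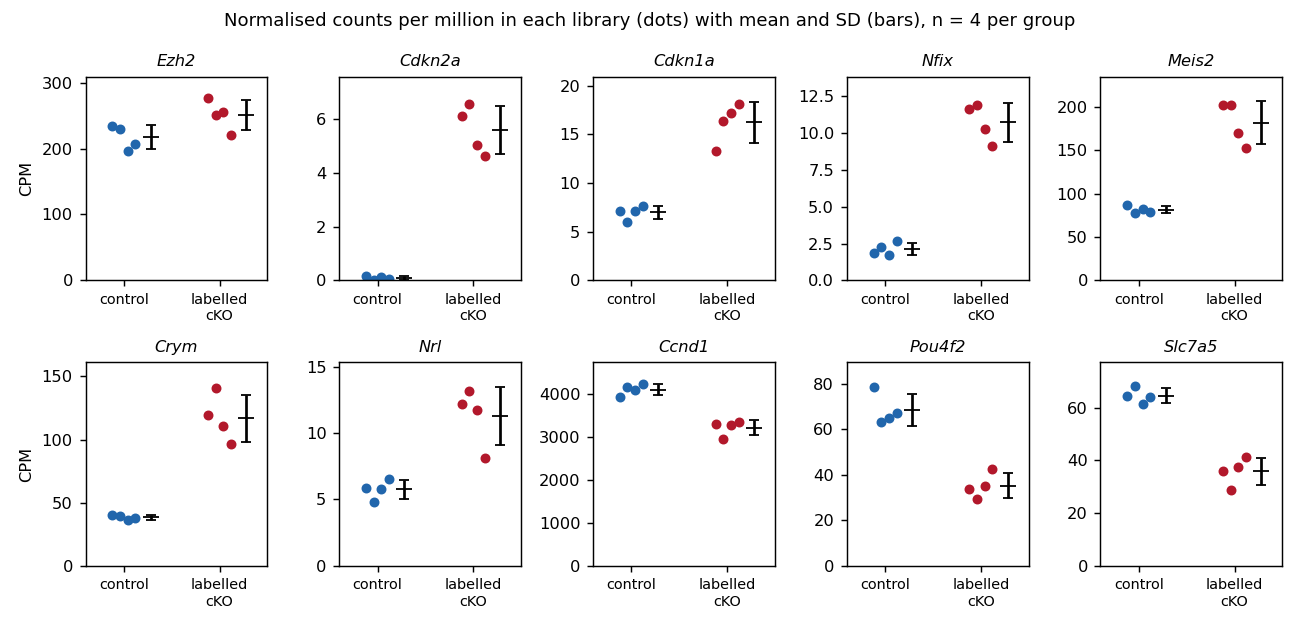
Each panel gives the CPM (y axis, from 0) of a gene in the 4 control and 4 labelled-cKO libraries as dots, with the group mean and SD as a bar. The groups overlap for Ezh2 and are apart for the other 9 genes shown, with Cdkn2a between 4.63 and 6.54 CPM in the labelled-cKO libraries and at most 0.150 CPM in the controls.

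Markers of neurons moved in both directions. Of 19 retinal ganglion cell genes, 2 were higher, 8 lower and 9 not called (3 and 11 adjusted over the list alone; median -0.15; camera adjusted p = 0.00429; adjusted p = 0.381 with an estimated correlation). The camera call also ended without the 2 libraries with lens crystallin counts, at a median of -0.13 and an adjusted p of 0.0825, where the range over 17 alternatives was 0.000139 to 0.381. Pou4f2, an early ganglion cell transcription factor, fell from 68.5 ± 7.10 to 35.2 ± 5.44 CPM (log2 -0.96, SE 0.10, edgeR adjusted p = 1.07e-05), and Eomes was at log2 -0.67. The higher members were the related factor Pou4f3 (log2 1.24) and the surface protein gene Thy1 (1.45). Of 12 amacrine cell genes, 5 were higher, 1 lower and 6 not called (6 and 1 adjusted over the list alone; median 0.29; camera adjusted p = 1.18e-05; 0.0317 with an estimated correlation). Meis2 rose from 81.5 ± 4.28 to 181 ± 24.9 CPM (log2 1.15), Gad1 by log2 1.08, Bhlhe22 by 0.71 and Tfap2c by 0.56. Of 8 horizontal cell genes, 3 were higher, 2 lower and 3 not called (3 and 2 adjusted over the list alone; median 0.05; camera adjusted p = 0.210), with Calb1 at log2 1.55, Lhx1 at 0.98 and Tfap2b at 0.35. The lower members were Foxn4 at log2 -0.35, a call that ended with the male libraries alone at -0.24, and Onecut1 at -0.34, named here after its values were seen, a call lost in 7 of 22 alternatives.

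Most rod and pan-photoreceptor genes tested were higher. Of 12 rod and pan-photoreceptor genes, 10 were higher, 0 lower and 2 not called (12 and 0 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 2.82e-09; adjusted p = 0.101 with an estimated correlation). The rod factor Nrl was at 11.3 ± 2.19 against 5.75 ± 0.737 CPM (log2 0.97), Nr2e3, which acts with Nrl in rods, at 2.87 ± 1.24 against 0.271 ± 0.277 CPM (log2 3.26, SE 0.52), Aipl1 at log2 0.86 and Crx at 0.30. Of 8 cone genes, 4 were higher and 4 not called (4 higher and 2 lower adjusted over the list alone; median 0.25; camera adjusted p = 0.0998), with Rxrg, a nuclear receptor gene, at log2 0.34 and the cone opsin gene Opn1sw at 0.97, a call that ended with the male libraries alone at log2 0.88. The cone list passed without cKO replicate 4 (camera adjusted p = 0.00105) and without control replicate 1, 2 or 3 (0.0414, 0.0426 and 0.0452), in a range of 0.00105 to 0.386 over 17 alternatives, and with fry (0.0292). Of 7 bipolar cell genes, 2 were higher and 5 not called (3 and 0 adjusted over the list alone; median 0.24; camera adjusted p = 0.159, fry adjusted p = 0.0134), with Lhx4 at log2 0.39.

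**Figure D4:**
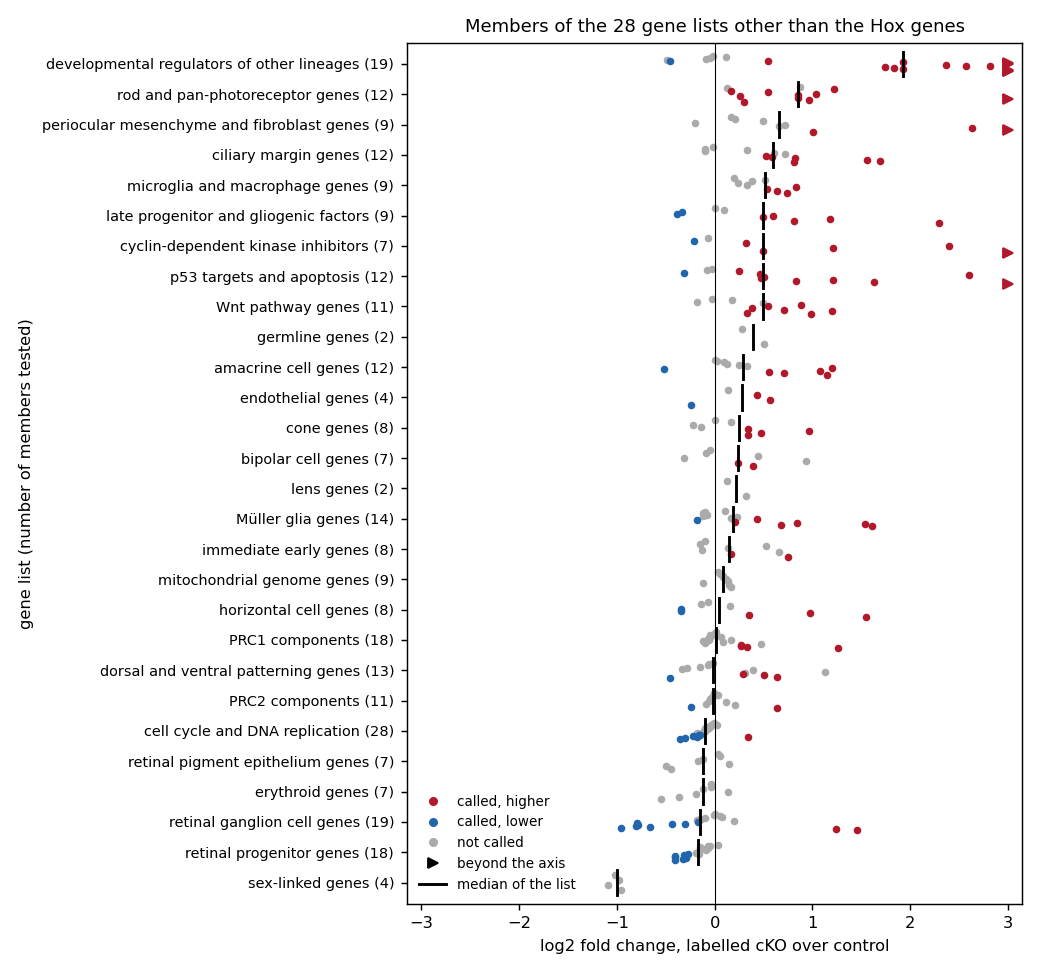
Each dot is a tested member of a gene list fixed before the data were examined, with its log2 fold change of labelled-cKO over control libraries on the x axis and 28 lists on the y axis; red and blue mark called members, triangles members beyond the axis, and black bars medians. Medians run from -0.998 for the sex-linked genes to 1.92 for developmental regulators of other lineages, and the Hox genes are left out.

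Among PRC1 components, 4 of 18 were higher, 0 lower and 14 not called (5 and 0 adjusted over the list alone), with a median of 0.01 and a mean of 0.14 (camera adjusted p = 0.0147; adjusted p = 0.150 with an estimated correlation). Bmi1, a core PRC1 subunit, was at 223 ± 15.1 against 93.3 ± 1.27 CPM (log2 1.26, SE 0.05, edgeR adjusted p = 1.43e-09), and Cbx8 at log2 0.33. The list median lay between 0.0033 and 0.044 over the 8 left-out libraries, with the highest value without control replicate 3 and the lowest without control replicate 4.

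The strongest decreases included several genes of amino acid transport. The transporter genes Slc7a3 and Slc7a5 were at log2 -1.30 and -0.85 (SE 0.12 and 0.09; edgeR adjusted p = 4.53e-06 and 1.05e-05). Slc7a11 was at 5.33 ± 0.337 against 10.7 ± 1.01 CPM (edgeR adjusted p = 1.07e-05). Slc7a5, a large neutral amino acid transporter, fell from 64.5 ± 2.77 to 35.8 ± 5.22 CPM. Chac1, a glutathione-degrading enzyme gene, was at log2 -1.08. Trib3 was at -1.07, a call lost in 8 of 22 alternatives. The largest decrease was that of Alms1-ps2 (log2 -3.18, from 2.16 ± 0.328 to 0.244 ± 0.134 CPM), a transcribed pseudogene that may share reads with Alms1. Alms1-ps2 and Zc3hav1 lie on chromosome 6, as Ezh2 does. By the labels, only the cKO libraries carry the null allele. Differences linked to that allele therefore cannot be told apart from loss of Ezh2. The remaining genes named for their decrease were Gm15631 (-1.25), Tnfrsf25 (-1.14, a call that ended without the 2 libraries with lens crystallin counts, at -0.90) and Ttc29 (-1.04).

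Lists for other cell types and RNA quality were measured in the same way. Of 9 microglia and macrophage genes, 4 were higher and 5 not called (6 and 0 adjusted over the list alone; median 0.52; camera adjusted p = 0.000970; adjusted p = 0.150 with an estimated correlation). Their summed level was 51.5 ± 3.01 against 37.7 ± 3.70 CPM (SD, n = 4), with P2ry12 at log2 0.74 and C1qb at 0.63. Without the 2 libraries with lens crystallin counts the list median was 0.29. Of 4 endothelial genes, 2 were higher, 1 lower and 1 not called (2 and 1 adjusted over the list alone; camera adjusted p = 0.637), and of 8 immediate early genes, 2 were higher and 6 not called (3 and 0 adjusted over the list alone; camera adjusted p = 0.297, fry adjusted p = 0.0176). No member was called among 7 pigment epithelium genes, 7 erythroid genes, 9 mitochondrial genes, 2 lens genes and 2 germline genes by edgeR, over the list alone as well; 0 had an unadjusted p under 0.05 and 0 were called by DESeq2 or limma-voom. Their camera adjusted p ran from 0.591 to 0.731, and fry gave the germline list an adjusted p of 0.0471 in the higher direction. The mitochondrial list passed as higher without control replicate 1 (median 0.31, camera adjusted p = 0.0414, range 0.0414 to 0.999). The erythroid list passed as lower with the male libraries alone (median -1.20, camera adjusted p = 0.00545, range 0.00541 to 0.892). Both passed at the preset correlation of 0.01, whereas the correlation estimated with all libraries was 0.805 for the mitochondrial and 0.945 for the erythroid list. The members of each list thus moved nearly as 1 measurement, and these adjusted p values overstate the evidence. The summed lens level was 13.3 CPM in cKO replicate 2, 17.6 CPM in control replicate 1 and at most 4.76 CPM in the others. The 4 Y-linked members of the sex-linked list were not called by edgeR (0 at an unadjusted p under 0.05) or DESeq2, were all called by limma-voom, and had a median of -0.998 (camera adjusted p = 0.0363; adjusted p = 0.415 with an estimated correlation). The median was -1.75 without cKO replicate 1, -0.60 without cKO replicate 2, -0.60 without cKO replicate 3 and -0.040 with male libraries alone, where the adjusted p was 0.461 in a range of 0.00507 to 0.475 over 17 alternatives.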

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

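The tests in this part on mesenchyme cells, microglia, embryo sex in the Hox and lineage genes, a wrong group label, exon loss and the unseen amino acid genes alone were chosen only after the results they bear on were seen; the count of splits and the tests on all the amino acid genes were written beforehand. The search for a library far from the other 3 of its group covered named genes with more than 3 control counts, 11 list sums, depth and mitochondrial rRNA; it found 15 in 220 groups, and chance gives about 11.

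Several single libraries stood apart from their group. In log2 CPM, Bmi1 was 6.57 in control replicate 3 (others 6.54), Lhx1 0.83 and Lhx4 4.73 in control replicate 1, Nr4a1, an immediate early gene, 0.85 in control replicate 4, and Gad1 0.23 in control replicate 2 and 1.66 in cKO replicate 4. Ccnd1 was 11.52 in cKO replicate 2, Nr2e3 0.24 (others at least 1.74) and Tbx5 4.49 in cKO replicate 4, and Pecam1, an endothelial gene, -1.79 and Postn 0.13 in cKO replicate 1. Summed lens genes were 13.3 CPM in cKO replicate 2 and 17.6 CPM in control replicate 1, where the crystallin genes Cryaa and Cryba1 had 30 and 27, and 53 and 46 counts. Summed endothelial genes were 361 CPM in control replicate 4, and summed Hox genes 66.6 CPM in cKO replicate 2.

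A signal also stood in genes the filter left untested. The 5 untested Hox genes, all of the Hoxa cluster, summed to 211 counts in the labelled-cKO libraries and 1 in the controls. The 7 untested regulators of other lineages summed to 233 and 61 counts, and each labelled-cKO library lay above each control for both sums.

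The first pattern is the rise of Hox genes and regulators of other lineages. Cells of mesenchyme would bring their collagens. The median log2 fold change of Col1a1, Col1a2 and Col3a1 was 0.21, and their highest 95% upper limit was 1.86. This limit lay under the fitted 2.63 of Foxc1, the smaller of Twist1 and Foxc1. The comparison left out the spread of Foxc1 itself (SE 0.35). Both genes belong to the mesenchyme list and not to this pattern. The test therefore does not decide whether mesenchyme cells contribute to the regulators. For the Hox genes, the collagens can be set against them directly. The lowest called Hox gene was at 4.40, with members at 0 in the controls at their bound, above the collagen limit of 1.86. These values argue against more cells that bring collagen as the source of the Hox genes. Mesenchyme cells with little collagen are not covered. Embryo sex is argued against, since all 31 called members were still called with the male libraries alone. Their median was 4.86 with the male libraries alone and 5.03 with all libraries, with members at 0 in the controls placed at their bound. More microglia are argued against too, since they would raise no gene they bring by more than their own genes. The highest 95% upper limit of the microglia genes was 1.44. The called Hox genes had a median of 5.66 (18 of 18 above that limit) and the called regulators a median of 2.57 (12 of 13 above it). The comparison left out the spread of the called members themselves. It also left out the 5 regulators not called and the 1 lower. Regulators with few counts need a large rise to be called, so their share above the limit was in part fixed by this selection. Mesenchyme cells stay open for the regulators, as do mesenchyme cells with little collagen for the Hox genes. Cells of other types stay open for both. So does loss of Ezh2 function in the labelled-cKO tissue, which was not tested apart from the group labels.

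The second pattern is the Ezh2 count that was not lower. A single library with the wrong label would put its Hox level in the range of the other group, and 0 libraries did so (48.1 CPM or more against 0.268 CPM or less). A transcript that lacks part of its exons but is still counted over the gene cannot be told apart from an intact one here: the whole-gene log2 fold change of 0.21 holds no counts per exon, and the explanation stays open.

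The third pattern is the lower level of 24 of 36 amino acid and ATF4-target genes, of which 15 were picked because they were seen to be lower, described under the other observations. Embryo sex as the whole cause is argued against by a median of -0.30 with the male libraries alone, against -0.35 with all, and the share of mitochondrial rRNA by a median of -0.34 with that share as a covariate. These medians include the 15 picked genes; the 21 unseen genes had medians of -0.17, -0.14 and -0.15 in the same order. With male libraries alone 17 of the 24 calls remained, 3 of the 9 among unseen genes, so part of the calls was not kept with fewer libraries. Differences in diet, dissection time or cell stress between embryos were not tested and stay open beside the genotype.

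In the count of called genes, 1 of the 35 splits of the 8 libraries into 4 and 4 reached 1773, the real split. The highest of the other splits gave 3. A share of 1 in 35 is the smallest that this count can reach. The other splits mix the groups, so the group difference adds to the spread within them and lowers their calls. The splits therefore show that the calls follow the group labels, but they do not exclude chance. For called lists chance cannot be excluded in this way, since 3 of the 35 splits gave as many as the real 17, the highest of the other splits also giving 17; the splits that keep 3 libraries of a group together gave 8 to 17 lists and the evenly mixed ones 1 to 6.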

How the results depend on the processing

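The alternatives on sex, lens counts, X and Y genes and mitochondrial rRNA were chosen after seeing the data. No called gene changed direction in any alternative. Both female libraries are cKO, so sex as a covariate again sets the 2 male cKO libraries against the controls. It is therefore no check apart from the male libraries alone: Aebp2 was at log2 -0.14 in both. Counts of alternatives that lost a call include both. Genes higher (1253) became 800 with male libraries alone, 795 with sex as a covariate, 801 at an adjusted p under 0.01 and 294 at 2-fold or more; genes lower (520) became 255, 246, 200 and 13 in the same order, 273 with library size alone and 323 without the 2 lens libraries. Leaving out each library gave 1008 to 1233 higher and 329 to 667 lower genes. All other alternatives stayed within 1.5 times. Pairs of cKO libraries set against the 4 controls gave 1055, 1114 and 1195 calls where cKO replicate 4 was in the pair, the male pair being the lowest of these, and 1406, 1610 and 1617 where it was not, with the female pair the highest; the lower count with male libraries is therefore not shown to come from sex. Ezh2 passed the threshold with DESeq2 (log2 0.20, adjusted p = 0.0423) and 1 surrogate variable (0.24, 0.0280), and its range over left-out libraries was 0.16 to 0.26, with 0.0129 (without cKO replicate 4) to 0.206 for the adjusted p; over all 22 alternatives the adjusted p ran to 0.268. The replicate block gave Ezh2 0.21 (edgeR adjusted p = 0.0250), kept 1560 of 1773 calls and added 116. Same-numbered libraries correlated at 0.118, -0.0234, -0.228 and 0.177 in their deviations, none best with its own number. No pairing by number was thus detected, though a weak pairing under other differences between libraries is not excluded.

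Lists higher (13) became 8 with an estimated correlation; lists lower (4) became 1, 2 with fry and 2 without the lens libraries; left-out libraries gave 13 to 15 and 3 to 4. The direction given by camera or fry, though not always the sign of the median, turned for lists without a call: PRC2 (median -0.017 with fry, 0.0090 with male libraries, 0.0091 with sex as a covariate, -0.011 without the lens libraries; -0.038 to 0.018 over left-out libraries), lens (0.15 with male libraries; 0.063 to 0.30), pigment epithelium (-0.38 to 0.18), erythroid (-0.61 to 0.54) and mitochondrial genes (-0.046 to 0.31). So did Pecam1 (-0.0066 with limma-voom, -0.019 with 1 surrogate variable, -0.27 with male libraries, -0.27 with sex as a covariate; -0.033 to 0.49). The erythroid list passed as lower with male libraries (median -1.20, camera adjusted p = 0.00545) and with sex as a covariate (camera adjusted p = 0.00541, the lowest in a range up to 0.892). These 2 alternatives make the same comparison at the preset correlation, far below the 0.945 estimated for this list with all libraries. Fry called the cone (0.0292), bipolar (0.0134), germline (0.0471) and immediate early (0.0176) lists higher, which camera did not, and did not call the ganglion cell (0.0569) and sex-linked (0.159) lists. The cause was not tested for Ezh2 and the lists.

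Of 98 called named genes, 80 passed at an adjusted p under 0.01 and 45 were at 2-fold or more. In the 22 other alternatives, of which 4 genes were tested in 21, 77 kept their call wherever tested and 21 lost it in at least 1: Aebp2, Aldh1a1, Btg2, Ccne1, Cldn5, Cx3cr1, Egfl7, Foxn4, Gnat2, Gngt2, Junb, Kdr, Mcm3, Neurog2, Opn1sw, Prkca, Rybp, Tnfrsf25, Trib3, Tyrobp and Vax1. Of the named genes that were not called, Cabp5 passed without cKO replicate 4, Postn without cKO replicate 1, and Nr4a1 without cKO replicate 2, without control replicate 4 and with mitochondrial rRNA as a covariate. The planned sex covariate needed both sexes in both groups and was not run as planned, and the alternatives for normalized values were not run because the table holds counts. Depth limits the folds of the 15 Hox genes with no control count to lower bounds.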

Other observations

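The members of the 3 added lists were chosen after a look at the table of all genes; each list was split into genes already seen there and genes not yet seen, and the tests were written before the unseen genes were looked at. Of the imprinted genes, Dcn was later taken out of the unseen part because the mesenchyme list had already shown it. With an estimated correlation, the Benjamini-Hochberg adjustment over the 3 unseen lists gave all of them the same adjusted p of 0.0667. This tied value is set by the largest p of the 3 and does not give the strength of each single list.

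Several genes of amino acid transport and synthesis and other targets of the stress factor ATF4 were lower. Of 36 such genes, 24 were lower, 0 higher and 12 not called (edgeR), with a median of -0.35, but 15 of the 24 were picked because they were seen to be lower. Among these were Asns (log2 -0.51), Cth (-0.65) and Atf5 (-0.81). Of the 21 unseen genes, 9 were lower and 12 not called. The lower ones included Pycr1 (-0.47), Ddit3 (-0.34) and Atf4 itself (-0.17). The median of the 21 was -0.14 (camera adjusted p = 4.03e-06 over the 3 lists; adjusted p = 0.0667 with an estimated correlation), so the call is lost with that correlation. Without Trib3, which the report also names for its decrease, 8 of 20 were lower, in a test added after these values were seen. Camera gave an adjusted p of 1.33e-05, and again the tied 0.0667 with an estimated correlation. The tied value cannot show what leaving out Trib3 changes.

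Some genes of a list of MHC class I and interferon-response genes rose. H2-K1 went from 2.53 to 13.3 CPM (log2 2.37) and was seen beforehand, as were Zc3hav1 (3.31, higher) and Herc6 (-0.82, lower). Of 14 unseen genes, 4 were higher and 10 not called: H2-D1 (log2 1.02), Tap1 (1.67), Tap2 (1.70) and B2m (0.52). The unseen median was 0.064 (camera adjusted p = 0.0101; adjusted p = 0.0667 with an estimated correlation), and the antigen presentation genes Tapbp (0.08) and H2-T23 (0.84) and the interferon-response gene Irf9 (0.02) were not called. Summed microglia genes, whose cells also express MHC class I, were 51.5 against 37.7 CPM.

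Imprinted genes moved both ways. Igf2 (log2 1.52) and its antisense Igf2os (2.57) were seen beforehand; their models overlap by 98 bases, and reads shared between them are not excluded, since the strand of counting is not given in the sources used here. Of 20 unseen genes, 6 were higher, 2 lower and 12 not called, with a median of 0.10 (camera adjusted p = 0.00531; adjusted p = 0.0667 with an estimated correlation). Mest (0.64), Rian (0.56) and Dlk1 (1.63) were higher, Grb10 (-0.34) and Plagl1 (-0.42) lower, and H19 (-0.02), the neighbour of Igf2, was not called.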
